A study of Caenorhabditis elegans with 9 samples.

How the data were processed

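Whole adult worms of Caenorhabditis elegans N2 were grown for 4 days in microgravity, at 1G on the station, or at 1G on the ground. Total RNA was labelled with Cy3 and hybridised to Agilent one-colour arrays, 3 per group. The labels give the same growth protocol for all samples, the ground samples included, so ground conditions are known only as a 1G control.

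Each deposited file held spot intensity values of one array, made per the file headers with Agilent Feature Extraction 10.7.3.1 from Cy3 scans of design 020186. Per the file headers, spatial and multiplicative detrending were on and local background correction was off. The background value used for a spot was that of the fitted spatial surface, and nothing was scaled between arrays. The deposited value table holds log2 values. Its scale, centring and direction are not given in the sources used here. Set against the scanner signals, at least 99.955% of its values in every column lay within 0.05 of log2 processed signal minus the array's 75th percentile, centred per probe on the median of the 3 onboard 1G arrays. Its column medians were 0.21, 0.17 and 0.17 in microgravity, 0 in each onboard 1G column, and 0.05, 0.03 and 0.04 in ground 1G. It lists 35549 of the 43603 non-control probes. The deposited spot flags, values of 0 or 1 per the file headers, marked spots well above background, saturated or outliers.

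Spots of a probe were averaged, 427 probes with outlier flags were left out, and control spots were not used. Values were log2 processed signal minus the array's 75th percentile. A probe was kept if well above background on all arrays of at least 1 group, which left 37763 probes, of which 32047 were named. Probes of a gene were averaged. Probes that match several genes were used only for genes without a probe of their own (480 genes, called shared). Names came from systematic names for 35256 probes, from gene symbols for 969 and from accessions for 65, through a table of NCBI gene names of assembly WBcel235. 7301 probes matched no gene, and 12 matched several genes and were given no name. Probes that match several genes, named or not, numbered 1242. Coordinates of that assembly were not used. On each array between 85.4% and 89.3% of spots were well above background, and array number limits the precision.

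Groups were compared with limma 3.58.1 (lmFit and eBayes, R 4.3.3) in one fit of all 9 arrays, with contrasts of microgravity with onboard 1G, microgravity with ground 1G, and onboard 1G with ground 1G. Benjamini-Hochberg adjustment ran over all genes of a contrast at a threshold of 0.05. The fit had 6 residual degrees of freedom and a prior of 1.93. Gene lists (38, with at least 5 measured genes) were tested with camera at a preset correlation of 0.01, with the correlation estimated from the residuals and with fry as alternatives. Array measures were compared with exact two-sided permutation tests, which with 3 against 3 arrays give no p below 0.1. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

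The lists, the tests and the alternatives were fixed before the data were examined. The alternatives were normexp on mean and background signals with an offset of 50, which by construction draws changes of dim probes toward 0, quantile normalization, median centring, the value table, other filters and probe rules, fits of 6 arrays, a trend in the prior, a replicate block, a 2-fold threshold and leaving out each array. Scaling to E1A spike-ins was added after the data had been seen. The spike-in rule, a log2 signal over 8 on all arrays, kept 7 of 10 probes and was also set after the values were seen. With all 10 probes the shift was −0.56 in microgravity minus onboard 1G, −0.57 in microgravity minus ground 1G and −0.01 in onboard 1G minus ground 1G.

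Genes named in the text followed a rule fixed beforehand. It takes the 8 highest and 8 lowest named genes per comparison whose groups do not overlap and that were measured in both groups, up to 3 per direction with only a bound, the 4 smallest p-values per list, and 20 genes named before in this field. Not every gene allowed by the rule is named. Genes outside it are said to be so.

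The steps were tested on simulated data for the comparison of microgravity with onboard 1G over 18075 genes, 200 of them changed. Recovery was 65% at a log2 change of 0.5, 91.2% at 1 and 95% at 2, with 4 false calls among 167. A list shifted by 0.5 was called and none of the other 37 was. The simulated genes varied independently of each other and held no slide effect. The test therefore does not cover lists of correlated genes or data in which most genes differ. Array slide as a block could not be fitted because each group lay on 1 slide of its own.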

Results

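Whole adult worms of Caenorhabditis elegans N2, the standard wild type, were profiled after 4 days of culture from the L1 larval stage. One group grew in microgravity on the International Space Station. A second group grew on the station at 1G (onboard 1G), and the last was a 1G control on the ground (ground 1G). Each group held 3 samples, and each sample was hybridised to its own one-colour Agilent array, so 9 arrays gave the relative level of 18075 genes. Between 85.4% and 89.3% of the spots on an array lay well above background, and no spot was saturated. The number of arrays limits the precision, and each value below is a log2 fold change ± its standard error from the fit (n = 3 arrays per group) unless stated otherwise. No label says that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. Each group lay on a slide of its own with a scan of its own, so slide and group cannot be told apart in any comparison.

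The 3 groups stood apart from each other. The first principal component held 80.6% of the variance and placed the ground 1G arrays between onboard 1G and microgravity. The second component, with 10.73%, set the ground arrays against both flight groups. Arrays of different groups correlated across genes at 0.900 to 0.925 for microgravity with onboard 1G, 0.960 to 0.977 for microgravity with ground 1G, and 0.966 to 0.972 for onboard 1G with ground 1G. By limma's moderated F test with Benjamini-Hochberg adjustment, 15646 genes (86.6%) differed among the groups. The E1A spike-ins, control RNAs added at labelling, were brighter against the array's 75th percentile in microgravity (2.75 ± 0.09, SD, n = 3) than in onboard 1G (2.12 ± 0.14) or ground 1G (2.27 ± 0.06). All changes below are therefore relative to the 75th percentile of each array. Scaled to the spike-ins instead, every gene moved by −0.63 in microgravity minus onboard 1G, −0.47 in microgravity minus ground 1G and 0.16 in onboard 1G minus ground 1G.

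**Figure D1:**
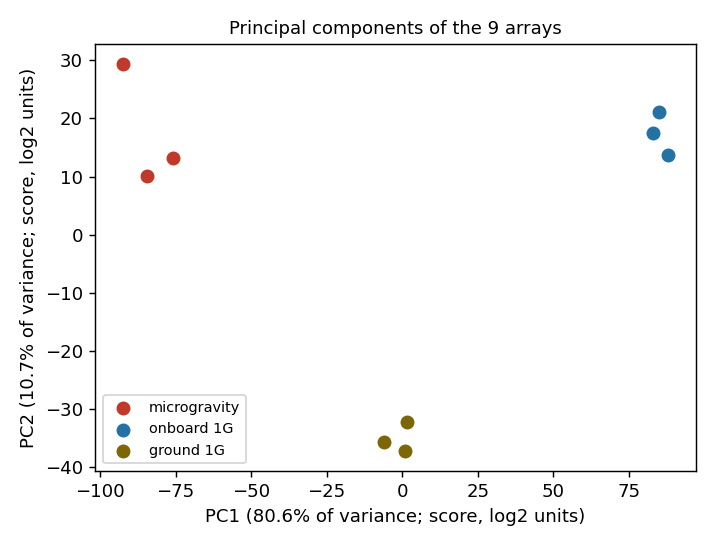
Scores of the 9 arrays on the first 2 principal components of log2 relative signal over the genes measured. Points are arrays coloured by group; the ground 1G arrays lie near 0 on the first component, which holds 80.6% of the variance, between the flight groups.

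The comparison of microgravity with onboard 1G asks whether gravity level in orbit goes with a difference in expression. Sperm genes and cuticle collagens were lower in microgravity, and oocyte, embryo and yolk genes were higher. All 24 measured major sperm protein genes, which encode the cytoskeletal protein of nematode sperm, fell, with a median of −3.70. The lowest gene under the naming rule was hsp-16.2, a small heat shock protein, at −6.34 ± 0.12 (80.9-fold lower). The vitellogenin vit-3, a yolk protein made in the adult intestine, rose by 2.39 ± 0.08 (5.3-fold).

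Reproductive genes moved in opposite directions by class. Of 37 measured spermatogenesis genes outside the major sperm proteins, 30 fell and 4 rose (median −2.75, camera adjusted p = 1.1e-08, adjusted p = 0.448 with an estimated correlation, and a median of −1.47 with normexp). Among them were cpb-2, a spermatogenesis RNA regulator (−4.06 ± 0.08), and spe-19, needed for sperm activation (−3.45 ± 0.09, −1.47 with normexp). In the major sperm protein list (camera adjusted p = 3.8e-08, adjusted p = 0.500 with an estimated correlation), msp-142 fell by 4.17 ± 0.31 and msp-63 by 3.98 ± 0.30. These genes are near-identical copies and 6 of the 24 were read only by probes that match several genes, so they are not independent measurements. Of 33 oocyte and eggshell genes 32 rose and none fell (median 0.76, adjusted p = 9.4e-07, adjusted p = 0.471 with an estimated correlation), with chs-1, the eggshell chitin synthase, at 0.80 ± 0.04 and mbk-2, a kinase of the oocyte-to-embryo transition, at 0.97 ± 0.06. Of 28 genes first transcribed in embryos, 23 rose and 2 fell (median 1.18, adjusted p = 0.00067, adjusted p = 0.471 with an estimated correlation, and a median of 0.70 with normexp), with pes-10 at 2.85 ± 0.08 (1.70 with normexp) and hnd-1 at 2.02 ± 0.06. All 6 vitellogenins rose (median 0.86, adjusted p = 0.0092, adjusted p = 0.471 with an estimated correlation), and vit-2 was at 0.65 ± 0.06 (0.33 with quantile normalization). Of 43 germ line genes 38 rose and 1 fell (median 0.52, adjusted p = 4.2e-05, adjusted p = 0.471 with an estimated correlation, but −0.11 and not called with spike-in scaling), with zim-1 at 0.82 ± 0.05 and spo-11, the meiotic double-strand break enzyme, at 0.73 ± 0.05. The calls of chs-1, zim-1, spo-11 and vit-2 ended with spike-in scaling, where none changed sign.

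Cuticle collagens, the structural proteins of the worm's outer coat, were mostly lower in microgravity. Of 164 measured, 106 fell and 37 rose (median −1.13, adjusted p = 1.2e-06, adjusted p = 0.471 with an estimated correlation, and a median of −0.75 with normexp). The steepest were col-88 (−5.82 ± 0.22) and col-146 (−5.78 ± 0.55). Also among the lowest were idpc-3 (−5.94 ± 0.25) and abu-15, of the pharyngeal gene list (−5.34 ± 0.38). The serpin gene srp-10 was not well above background on any microgravity array and was at least 16.8-fold lower there (log2 fold change −1.39 with normexp). A lower bound of this kind sets the bright group's mean against the lowest signal well above background on each array, or the dim probe's own where that is higher. Such a bound holds only on the scale used here and not with normexp, which draws dim probes toward 0. Other genes highest in microgravity by the naming rule were gtnt-15 (3.72 ± 0.12, 1.39 with normexp), well above background on 2 of 3 onboard 1G arrays, smrn-1 (3.58 ± 0.33, 1.45 with normexp), on 1 of 3, sdz-30 (3.15 ± 0.12), and the F-box gene fbxc-24 (3.09 ± 0.08).

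The heat shock list as a whole did not pass the test, although single members fell steeply. The small heat shock gene hsp-16.41 fell by 5.43 ± 0.13, although its 2 probes gave −7.005 and −3.848. F44E5.5, an Hsp70-family gene read only by a probe that matches several genes, fell by 5.89 ± 0.14. Of the 30 measured genes in the list, 10 fell and 10 rose (median 0.02, mean −0.93, adjusted p = 0.27).

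In the respiratory chain list 32 of 45 genes fell and 6 rose (median −0.32, adjusted p = 5.7e-05, adjusted p = 0.471 with an estimated correlation, and a median of −0.15 with median centring), with isp-1, the Rieske protein of complex III, at −0.70 ± 0.05 and the cytochrome c gene cyc-2.2 at −4.55 ± 0.33. In the tricarboxylic acid cycle list 19 of 28 fell and 4 rose (median −0.24, adjusted p = 0.0059, adjusted p = 0.471 with an estimated correlation). There mev-1, of succinate dehydrogenase, was at −0.66 ± 0.04, fum-1, the fumarase, at −0.44 ± 0.05 (−0.27 with median centring), and cts-1, the citrate synthase, at −0.25 ± 0.08 (−0.08 with median centring, −0.45 with only probes above background on all arrays, −0.64 with the brightest probe, −0.45 with the value table and −0.16 without onboard 1G replicate 2), a call lost with median centring, in the fit of 6 arrays and without microgravity replicate 2 or 3. The list's own call was lost with median centring (median −0.07). In the fatty acid oxidation and fasting list 26 of 44 fell and 12 rose (median −0.45, adjusted p = 0.0036, adjusted p = 0.471 with an estimated correlation, and a median of −0.27 with normexp and −0.28 with median centring), among them the lipase gene lipl-3 (−2.16 ± 0.07, −1.297 with normexp) and daf-22, a peroxisomal thiolase (−1.13 ± 0.05).

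Neuropeptide and insulin genes were lower. Of 102 neuropeptide genes 83 fell and 5 rose (median −0.70, adjusted p = 1.3e-12, adjusted p = 0.448 with an estimated correlation), with nlp-3 at −0.91 ± 0.04 and flp-27 at −1.02 ± 0.05, whereas the list of general neuronal genes had a median of −0.02 and was not called (11 rose, 14 fell, adjusted p = 0.61). In the insulin list 30 of 48 fell and 11 rose (median −0.58, adjusted p = 0.002, adjusted p = 0.471 with an estimated correlation, and a median of −0.36 with normexp). The insulin-like peptide genes ins-37 and ins-35 fell by 4.29 ± 0.15 and 0.63 ± 0.08, and ins-2 rose by 2.54 ± 0.11. The FOXO gene daf-16 was at 0.22 ± 0.07 (0.39 with median centring), a call lost with the brightest probe and in 3 of the fits that left out 1 array, and turned to −0.41 with spike-in scaling. Of 25 DAF-16 target genes 18 fell and 6 rose (median −0.40, adjusted p = 0.024, adjusted p = 0.531 with an estimated correlation, and a median of −0.23 with median centring, not called with spike-in scaling), with hsp-12.6 at −1.29 ± 0.08 and the superoxide dismutase gene sod-3 at −0.51 ± 0.11 (−0.31 with normexp, −0.34 with quantile normalization and −0.34 with median centring).

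The RNA interference, DNA damage and proteasome lists were higher, as were the germ line and oocyte lists (medians 0.52 and 0.76). Except for the oocyte list, these lists were not called in microgravity against ground 1G. In the RNA interference list 33 of 43 rose and 3 fell (median 0.41, adjusted p = 0.0021, adjusted p = 0.471 with an estimated correlation, but −0.22 and not called with spike-in scaling). The double-stranded RNA binding gene rde-4 was at 0.71 ± 0.05, a call that ended with spike-in scaling (0.08). rde-1 was at 0.36 ± 0.06 and dcr-1, which encodes Dicer, at 0.39 ± 0.05, and both turned negative with spike-in scaling. The Argonaute gene alg-3, known to act in spermatogenesis, fell by 4.52 ± 0.25. In the DNA damage and apoptosis list 42 of 43 rose and none fell (median 0.56, adjusted p = 6.8e-07, adjusted p = 0.471 with an estimated correlation, but a median of −0.07 with spike-in scaling, where the list was still called against the other genes), with egl-1, an activator of cell death, at 1.24 ± 0.04. ced-13, of the same class, was not well above background on any onboard 1G array and was at least 4.3-fold higher in microgravity (log2 fold change 0.93 with normexp). In the proteasome list 21 of 31 rose and 2 fell (median 0.24, adjusted p = 0.028, adjusted p = 0.448 with an estimated correlation, and a median of 0.41 with median centring, but −0.39 with spike-in scaling, and not called with normexp, quantile normalization or without microgravity replicate 3), and rpn-2 and rpn-5 stood at 0.46 ± 0.04 (0.29 with the brightest probe) and 0.38 ± 0.05, both negative with spike-in scaling.

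Muscle lists did not pass the test in this comparison, although single genes did. Of 12 thick filament genes 8 fell and 2 rose (median −0.33, adjusted p = 0.11). The body wall myosin genes myo-3 and unc-54 were at −0.78 ± 0.06 and −0.37 ± 0.09 (−0.20 with median centring), and unc-15, the paramyosin gene, at −0.52 ± 0.09. The call of unc-54 was lost with median centring. Of 20 thin filament genes 11 fell and 4 rose (median −0.20, adjusted p = 0.15), where act-4 was at −0.24 ± 0.06 (−0.07 with median centring and 0.00 with the brightest probe), a call lost with median centring and with the brightest probe. unc-89, the obscurin homologue, was at −0.12 ± 0.08 (adjusted p = 0.18). Among the other genes named beforehand, dbl-1, a TGF-beta ligand, fell by 0.59 ± 0.06, comt-4, of the catechol methyltransferase family, by 1.71 ± 0.13 and dat-1, the dopamine transporter gene, by 0.38 ± 0.08 (0.15 with normexp, 0.21 with quantile normalization and 0.21 with median centring). sir-2.1, a sirtuin gene, rose by 0.50 ± 0.06 but was at −0.13 with spike-in scaling. cat-2, the tyrosine hydroxylase gene, was at −0.02 ± 0.08 (adjusted p = 0.79).

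The remaining lists were not called. Each had members that rose and members that fell, though few mitochondrial ribosomal protein genes fell. Over all genes tested, 46.6% were called higher and 32.3% lower. Rose and fell counts were 11 and 9 of 25 for muscle attachment, 14 and 12 of 29 for tubulins and intermediate filaments, 5 and 12 of 23 for glycolysis, and 10 and 9 of 21 for fatty acid synthesis. They were 11 and 5 of 20 for basement membrane, 16 and 11 of 30 for the molting cycle, 12 and 9 of 29 for the organelle unfolded protein response, and 10 and 13 of 33 for oxidative stress. They were 3 and 5 of 15 for hypoxia, 8 and 8 of 21 for TGF-beta signalling, 7 and 8 of 24 for dopamine and catecholamine methyltransferases, and 18 and 14 of 43 for innate immunity. They were 51 and 49 of 134 for cytochrome P450 and UGT genes, 19 and 13 of 77 for cytosolic ribosomal proteins, and 31 and 4 of 67 for mitochondrial ribosomal proteins. Markers of other tissues gave 10 and 17 of 30 for intestine, 7 and 12 of 22 for pharynx, and 19 and 11 of 35 for hypodermis.

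By limma with Benjamini-Hochberg adjustment, 8421 genes were higher and 5845 lower in microgravity than in onboard 1G, of which 1786 and 2436 differed by 2-fold or more. The 3 values of each group did not overlap in 8287 and 5736 of these genes, which were picked by the test, so the count is no further evidence. Of the 38 lists 16 were called, and none of the calls held when the correlation was estimated from the data (lowest adjusted p = 0.448 with an estimated correlation). Other groupings of the same arrays, which keep part of the group difference, called up to 20 lists. The list calls therefore depend on the setting of the test. The correlation value alone does not explain the lost calls, since the proteasome list had an estimated correlation of 0.0043, under the preset 0.01. Counts adjusted over the list alone were the same for the called lists except for 20 fallen genes in the tricarboxylic acid cycle. The share of calls that were higher, 59.0%, was 67.9% with median centring and 14.5% with spike-in scaling.

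**Figure D2:**
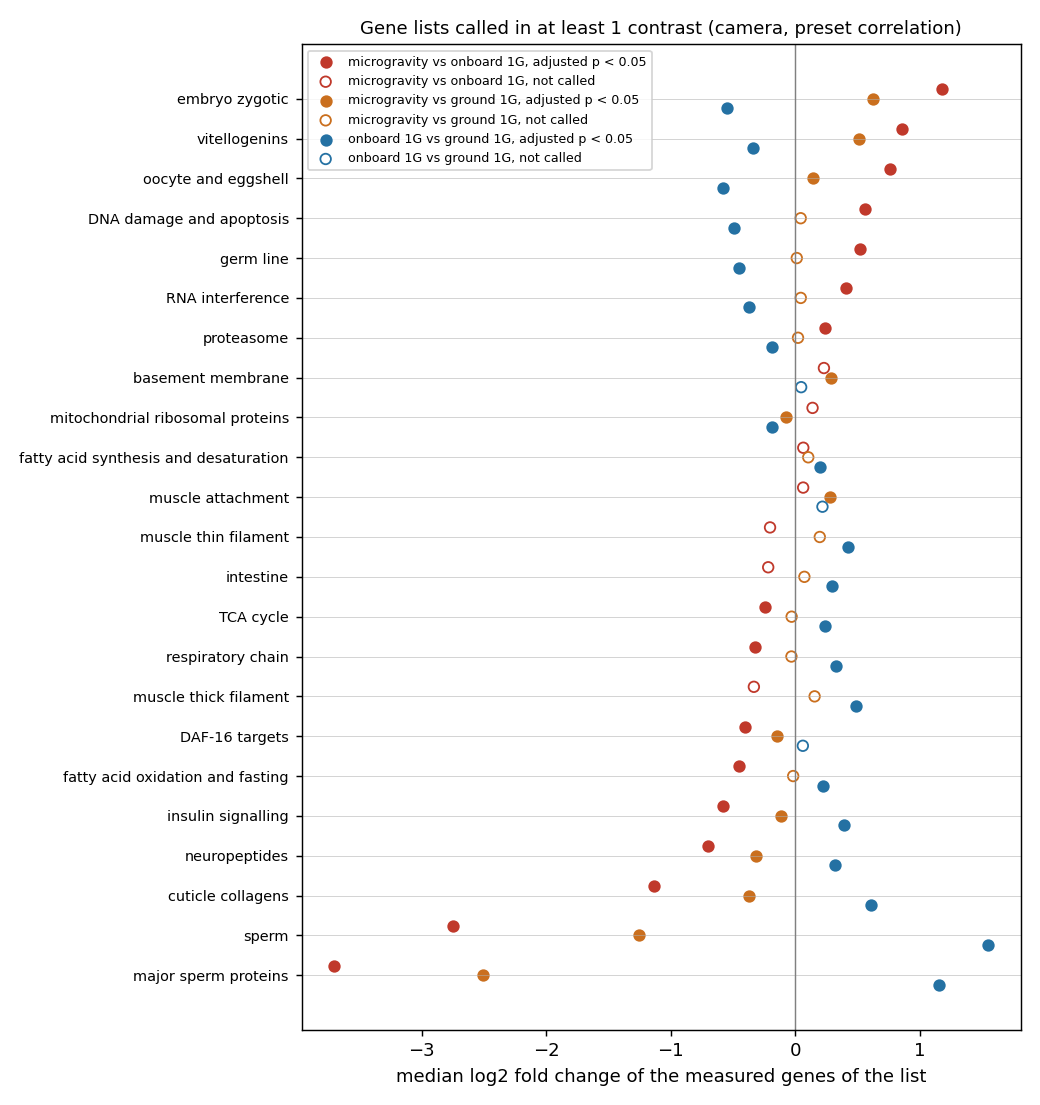
Median log2 fold change of the measured genes of each list called in at least 1 comparison, on the x axis, by list on the y axis. Filled points passed camera's test with a preset correlation and open points did not; no call held with an estimated correlation. Major sperm proteins lie lowest at −3.70 in microgravity vs onboard 1G. In that comparison the medians of the germ line, RNA interference, DNA damage and proteasome lists change sign with spike-in scaling. In microgravity vs ground 1G those of the muscle attachment, oocyte and basement membrane lists do. So do several medians of lists not called, up to 0.23 (basement membrane in microgravity vs onboard 1G).

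The comparison of microgravity with ground 1G covers the whole of the flight. It also takes in slide, scan and any difference in ground conditions, so the flight itself is not isolated. Sperm, collagen and neuropeptide genes were lower, and embryo, yolk and muscle attachment genes were higher, by smaller amounts than against onboard 1G in the sperm and collagen lists. All 24 major sperm protein genes fell (median −2.51, camera adjusted p = 1.2e-10, adjusted p = 0.689 with an estimated correlation), with msp-142 at −2.73 ± 0.31. In the sperm list 29 of 37 fell and 1 rose (median −1.26, adjusted p = 1.7e-10, adjusted p = 0.616 with an estimated correlation, and a median of −0.48 with normexp). Of 164 collagens 77 fell and 45 rose (median −0.37, adjusted p = 0.00085, adjusted p = 0.870 with an estimated correlation, and a median of −0.20 with normexp), with col-88 at −5.32 ± 0.22 and col-41 at −5.09 ± 0.20 (−3.26 with only probes above background on all arrays and −3.26 with the brightest probe). That call was lost with spike-in scaling.

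Of 28 embryo genes 21 rose and 2 fell (median 0.63, adjusted p = 0.0013, adjusted p = 0.689 with an estimated correlation), with pes-10 at 1.197 ± 0.08. All 6 vitellogenins rose (median 0.52, adjusted p = 0.0073, adjusted p = 0.689 with an estimated correlation, and a median of 0.28 with quantile normalization, not called after quantile normalization), with vit-3 at 1.09 ± 0.08 and vit-2 at 0.55 ± 0.06 (0.17 with quantile normalization), not called with spike-in scaling. In the oocyte list 12 of 33 rose and none fell (median 0.14, adjusted p = 0.034, adjusted p = 0.962 with an estimated correlation, and a median of 0.09 with quantile normalization), with mbk-2 at 0.41 ± 0.06 (0.26 with the brightest probe). That call was lost with normexp, quantile normalization, no filter on dim probes, the brightest probe and in 3 of the fits that left out 1 array, and both the median and mbk-2 were negative with spike-in scaling (−0.33 and −0.06).

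Muscle attachment genes, of the dense bodies and the dystrophin complex, were higher, with 18 of 25 raised and none lowered (median 0.28, adjusted p = 0.0065, adjusted p = 0.689 with an estimated correlation, but −0.19 with spike-in scaling). mig-15 was at 0.61 ± 0.07 and dyb-1, the dystrobrevin gene, at 0.49 ± 0.06, neither called with spike-in scaling. Of 20 basement membrane genes 14 rose and 1 fell (median 0.29, adjusted p = 0.0073, adjusted p = 0.689 with an estimated correlation, but −0.18 with spike-in scaling), with lam-1, a laminin beta chain gene, at 1.02 ± 0.07 (0.68 with normexp). Of 20 thin filament genes 12 rose and none fell (median 0.20, adjusted p = 0.088, not called), and of 12 thick filament genes 4 rose and 1 fell (median 0.16, adjusted p = 0.53, not called). myo-3 was at −0.07 ± 0.06, unc-54 at 0.18 ± 0.09 and unc-15 at 0.04 ± 0.09, none of them called, though unc-54 was called with normexp and with the replicate block. unc-89 was at 0.38 ± 0.08 and act-4 at 0.21 ± 0.06 (0.09 with quantile normalization). All 5 were negative with spike-in scaling, and the act-4 call was lost with quantile normalization and in 4 fits that left out 1 array.

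Neuropeptide genes fell in 67 of 102 cases and rose in 8 (median −0.32, adjusted p = 1.2e-10, adjusted p = 0.689 with an estimated correlation), with flp-3 at −1.27 ± 0.08 and nlp-3 at −0.48 ± 0.04. In the insulin list 19 of 48 fell and 10 rose (median −0.11, adjusted p = 0.03, adjusted p = 0.870 with an estimated correlation, and a median of −0.03 with normexp and −0.18 with quantile normalization, not called with normexp, spike-in scaling or in 2 fits that left out 1 array), where ins-37 was at −2.31 ± 0.15. Of 25 DAF-16 targets 11 fell and 6 rose (median −0.14, adjusted p = 0.027, adjusted p = 0.870 with an estimated correlation, and a median of −0.28 with quantile normalization, −0.24 with no filter on dim probes and −0.28 with the brightest probe, not called with spike-in scaling). There hsp-12.6 was at −2.102 ± 0.08 and sod-3 at −0.50 ± 0.11 (−0.31 with normexp). Mitochondrial ribosomal protein genes had a median of −0.07 (13 of 67 fell, 2 rose, adjusted p = 0.0073, adjusted p = 0.962 with an estimated correlation, and a median of −0.04 with median centring and −0.03 without ground 1G replicate 2, not called without microgravity replicate 1), and none passed when adjusted over the list alone.

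Single genes named by the rule that rose included pals-10 (2.53 ± 0.36), ilys-2, an invertebrate lysozyme (2.27 ± 0.05), sdz-6 (2.17 ± 0.46, 0.79 with normexp), well above background on 1 of 3 ground 1G arrays, and math-5 (1.93 ± 0.34, 0.78 with normexp). hsp-16.2 and hsp-16.41 fell by 3.67 ± 0.12 and 2.98 ± 0.13 (1.78 with the brightest probe). The SCP-like genes scl-12 and scl-13 fell by 5.64 ± 0.41 (3.31 with normexp) and 5.05 ± 0.67 (1.93 with normexp), and they were well above background on only 2 and 1 of 3 microgravity arrays. scl-11 was at least 31.4-fold lower (log2 fold change −2.32 with normexp). comt-4 fell by 2.95 ± 0.13 and dbl-1 by 0.32 ± 0.06.

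By limma, 6119 genes were higher and 3812 lower in microgravity than in ground 1G, of which 750 and 1367 differed by 2-fold or more. Of the 38 lists 12 were called, and none held with the correlation estimated from the data (lowest adjusted p = 0.616 with an estimated correlation). Adjusted over the list alone, fallen genes numbered 80 in collagens, 68 in neuropeptides and 12 in DAF-16 targets, and raised genes 6 in the oocyte list, 2 in sperm, 10 in neuropeptides and 7 in DAF-16 targets, with the other called lists as above. The share of calls that were higher, 61.6%, was 71.0% with normexp and 8.53% with spike-in scaling. Some lists called against onboard 1G were not called here by camera with the preset correlation. Their medians were 0.01 for germ line (adjusted p = 0.56), 0.05 for RNA interference (0.81), 0.04 for DNA damage (0.53) and 0.02 for proteasome (0.95). Medians were −0.03 for the respiratory chain (adjusted p = 0.15), −0.03 for the tricarboxylic acid cycle (0.53) and −0.02 for fatty acid oxidation (0.46).

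The comparison of onboard 1G with ground 1G covers the parts of flight other than microgravity. It also takes in slide, scan and any difference in ground conditions, so the design does not isolate those parts. Genes of sperm, muscle filaments, collagens and the respiratory chain were higher in onboard 1G. Genes of oocytes, germ line and embryos were lower, as was the DNA damage and apoptosis list. In the sperm list 31 of 37 rose and 5 fell (median 1.55, camera adjusted p = 1.3e-06, adjusted p = 0.300 with an estimated correlation), with cpb-2 at 2.34 ± 0.08. Of 24 major sperm protein genes 22 rose and none fell (median 1.16, adjusted p = 0.0015, adjusted p = 0.711 with an estimated correlation), with msp-63 at 1.44 ± 0.30.

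In the oocyte list 32 of 33 fell and none rose (median −0.58, adjusted p = 5e-08, adjusted p = 0.455 with an estimated correlation), with chs-1 at −0.74 ± 0.04. Of 43 germ line genes 42 fell and none rose (median −0.45, adjusted p = 9e-09, adjusted p = 0.300 with an estimated correlation), with spo-11 at −0.69 ± 0.05. Embryo genes fell in 18 of 28 cases and rose in 2 (median −0.55, adjusted p = 0.0031, adjusted p = 0.490 with an estimated correlation, and a median of −0.34 with normexp). Of the 6 vitellogenins 5 fell (median −0.34, adjusted p = 0.032, adjusted p = 0.518 with an estimated correlation), with vit-3 at −1.31 ± 0.08. The next 3 lists fell in the same comparison as the germ line and oocyte lists (medians −0.45 and −0.58). The DNA damage list fell in 42 of 43 genes with none raised (median −0.49, adjusted p = 9e-09, adjusted p = 0.300 with an estimated correlation), and ced-8 was at −1.24 ± 0.06. In the RNA interference list 35 of 43 fell and 4 rose (median −0.37, adjusted p = 0.00011, adjusted p = 0.345 with an estimated correlation), where rde-4, rde-1 and dcr-1 were at −0.58 ± 0.05, −0.38 ± 0.06 and −0.36 ± 0.05. The last 2 calls ended with spike-in scaling. Proteasome genes fell in 23 of 31 cases and rose in 1 (median −0.19, adjusted p = 0.0043, adjusted p = 0.300 with an estimated correlation, and a median of −0.34 with median centring, not called with spike-in scaling), with rpn-5 at −0.37 ± 0.05, which was not called with it either. Mitochondrial ribosomal protein genes fell in 43 of 67 cases with none raised (median −0.19, adjusted p = 0.0002, adjusted p = 0.603 with an estimated correlation, and a median of −0.12 with quantile normalization and −0.34 with median centring), with mrpl-48 at −0.50 ± 0.04.

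Muscle filament genes were higher in onboard 1G. In the thick filament list 10 of 12 rose and 1 fell (median 0.49, adjusted p = 0.011, adjusted p = 0.518 with an estimated correlation), where myo-3 was at 0.71 ± 0.06, unc-54 at 0.55 ± 0.09, unc-15 at 0.56 ± 0.09 and unc-89 at 0.50 ± 0.08. In the thin filament list 15 of 20 rose and 2 fell (median 0.42, adjusted p = 0.0051, adjusted p = 0.300 with an estimated correlation, and a median of 0.28 with median centring), with mup-2, a troponin T, at 0.73 ± 0.07, tnc-2, a troponin C, at 0.55 ± 0.06 and act-4 at 0.44 ± 0.06 (0.26 with the brightest probe). Respiratory chain genes rose in 33 of 45 cases and fell in 5 (median 0.33, adjusted p = 0.00011, adjusted p = 0.411 with an estimated correlation, and a median of 0.18 with median centring), with isp-1 at 0.54 ± 0.05. In the tricarboxylic acid cycle list 19 of 28 rose and 2 fell (median 0.24, adjusted p = 0.0089, adjusted p = 0.490 with an estimated correlation, and a median of 0.09 with median centring, not called with median centring), with mev-1 at 0.54 ± 0.04. Fatty acid oxidation genes rose in 25 of 44 cases and fell in 9 (median 0.23, adjusted p = 0.0074, adjusted p = 0.518 with an estimated correlation, and a median of 0.08 with median centring). Fatty acid synthesis genes rose in 12 of 21 and fell in 2 (median 0.20, adjusted p = 0.044, adjusted p = 0.300 with an estimated correlation, and a median of 0.13 with quantile normalization and 0.06 with median centring), a call lost in several alternatives and fits without 1 array.

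Collagens rose in 98 of 164 cases and fell in 17 (median 0.61, adjusted p = 2.9e-05, adjusted p = 0.518 with an estimated correlation). Neuropeptide genes rose in 68 of 102 and fell in 3 (median 0.32, adjusted p = 1.2e-07, adjusted p = 0.411 with an estimated correlation, and a median of 0.18 with median centring), with nlp-23 at 1.69 ± 0.07 (0.75 with normexp) and flp-12 at 1.24 ± 0.08 (0.49 with the brightest probe). In the insulin list 28 of 48 rose and 11 fell (median 0.39, adjusted p = 0.036, adjusted p = 0.603 with an estimated correlation, and a median of 0.23 with quantile normalization and 0.25 with median centring, a call lost with spike-in scaling, with no filter on dim probes and without ground 1G replicate 2). Intestinal genes rose in 19 of 30 cases and fell in 4 (median 0.30, adjusted p = 0.0071, adjusted p = 0.518 with an estimated correlation, and a median of 0.15 with median centring), with the acid phosphatase gene pho-1 at 0.97 ± 0.05 and the intermediate filament gene ifb-2 at 0.94 ± 0.05. hsp-16.2 and hsp-16.41 rose by 2.66 ± 0.12 and 2.45 ± 0.13. scl-12 and scl-13 fell by 5.46 ± 0.41 (3.60 with normexp) and 3.60 ± 0.67 (2.08 with normexp). scl-11 was at least 36.1-fold lower (log2 fold change −2.50 with normexp), and comt-4 fell by 1.24 ± 0.13. gadr-1, ces-2 and cpg-20 were at −2.43 ± 0.31 (−0.73 with normexp, −1.56 with only probes above background on all arrays and −1.56 with the brightest probe), −2.24 ± 0.18 and −2.196 ± 0.10, and sir-2.1 at −0.47 ± 0.06.

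By limma, 6298 genes were higher and 6879 lower in onboard 1G than in ground 1G, of which 2145 and 697 differed by 2-fold or more. Of the 38 lists 20 were called, and none held with the correlation estimated from the data (lowest adjusted p = 0.300 with an estimated correlation). Adjusted over the list alone, raised genes numbered 34 in the respiratory chain and 5 in RNA interference, and fallen genes 42 in mitochondrial ribosomal proteins, with the other called lists as above. The share of calls that were higher, 47.8%, was 37.1% with median centring and 66.6% with spike-in scaling.

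**Figure D3:**
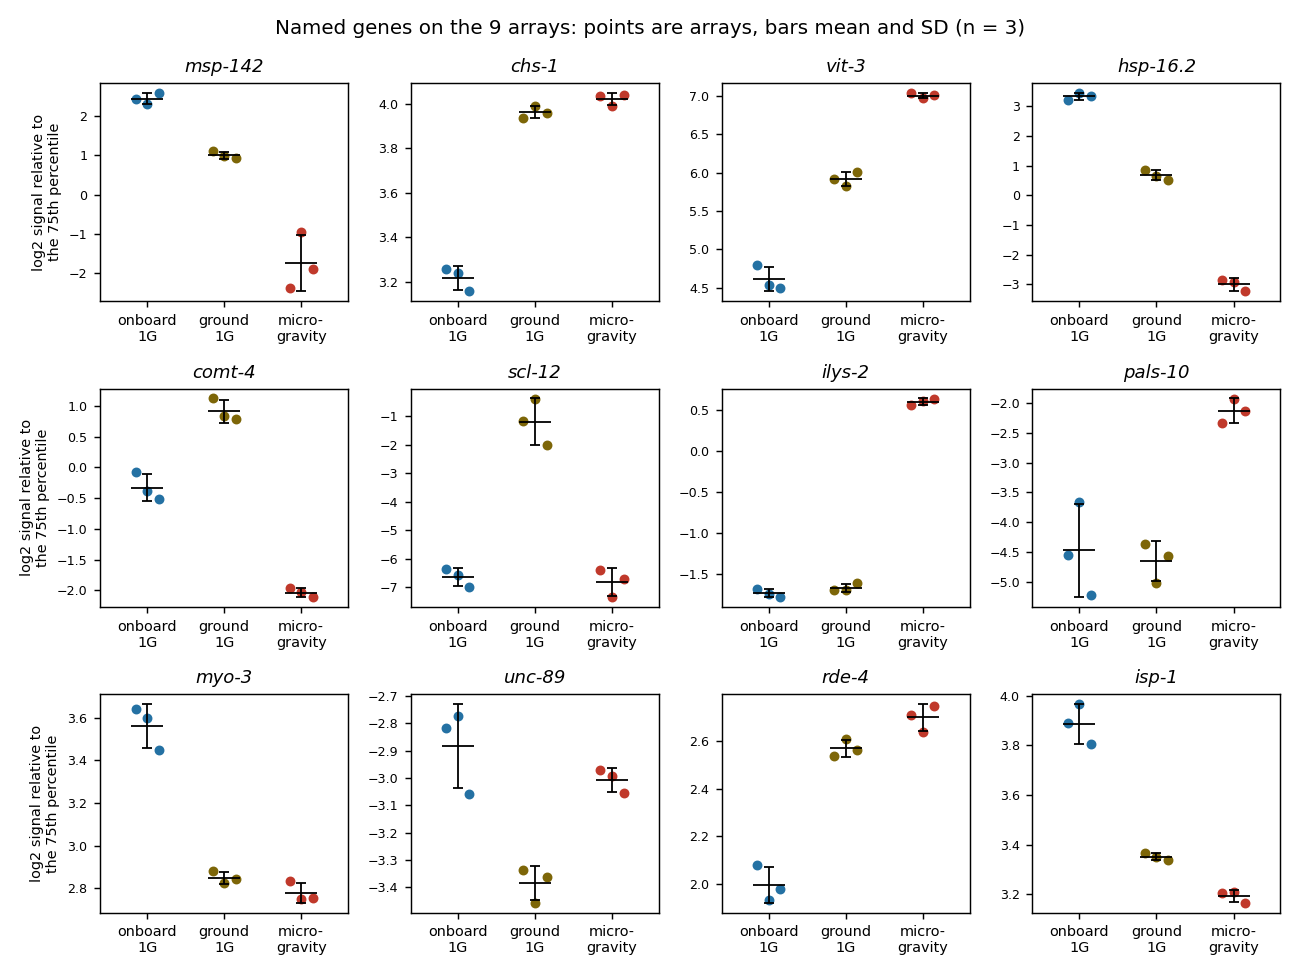
Log2 signal relative to the array's 75th percentile, on the y axis, for 12 named genes in the 3 groups on the x axis, with points for arrays and bars for mean and SD (n = 3). Ground 1G lies between the flight groups for msp-142, vit-3 and hsp-16.2, above both for comt-4 and scl-12, and the microgravity arrays lie apart from both 1G groups for ilys-2.

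The comparisons share arrays, so their calls are not independent of each other. Higher in microgravity than in either 1G group were 4502 genes, and lower than in either were 3249, where independent lists would give 2851 and 1233 and 50 simulations of unchanged groups, which leave out all effects, gave none. The first count leaves out the shared arrays. Higher in onboard 1G than in either other group were 4877 genes and lower 6239, against 2037 and 3205. Higher in both flight groups than on the ground were 1668 genes and lower 622, against 2132 and 1451. No array group can be split with 2 arrays in each part, so part of any excess may come from shared arrays. Among the 4222 genes that differed by 2-fold or more between microgravity and onboard 1G, the ground 1G mean lay between the flight means in 92.5%. Picking genes for a wide gap between the flight groups tends by itself to put the ground group between them. This share alone therefore does not show an order of the groups. The ground value stood at a median of 0.54 of the way from onboard 1G to microgravity.

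Where the deposited files give a probe position, it is on the ce4 (WS170) build. The probe for hsp-16.2 lay on chromosome V from 1804280 to 1804339, that for myo-3 on V from 12229572 to 12229631 and that for comt-4 on V from 2049199 to 2049258. The probe for col-88 lay on III from 41901 to 41960, that for msp-142 on II from 5797971 to 5798030, that for ilys-2 on IV from 2468445 to 2468504 and that for vit-3 on X from 3567700 to 3567810. Exon and intron annotation on that build was not used here. Log2 fold changes from the 2 probes of 1687 genes correlated across genes at 0.836, 0.766 and 0.777 in the 3 comparisons, in the order given above.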

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

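Except for the counts of other groupings, the tests in this part were chosen after the values they rest on, or related ones, had been seen. Labelling controls outside the gene measurements differed between groups. The E1A spike-ins minus the 75th percentile were higher in microgravity by 0.629 than in onboard 1G and by 0.474 than in ground 1G (exact permutation p = 0.1 each, the smallest 3 against 3 arrays allow, adjusted p = 0.1875 over 15 tests).

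Reproductive and cuticle genes were placed in the order onboard 1G, ground 1G, microgravity. Probes of one gene went the same way in 90.6% of 53 genes with at least 2 probes of their own (95% exact interval 79.3% to 96.9%). A slide effect acting on each probe by itself is argued against, since probes of different genes matched on the size of their mean change agreed in 43.1% to 62.7% (95% of 1000 draws, 51 of the 53 genes matched), and the limit for this test was changed more than once after the value was seen. The ground group stood at a median of 0.51 of the way from onboard 1G to microgravity (quartiles 0.31 and 0.77), where gravity as the only cause needs the 1G groups alike. The value cannot decide this, because the 1G groups lay on different slides and the genes were picked on the gap between flight groups. Developmental age of the cultures stays open. The ground mean lay between the flight means in 83.7% of the 233 genes, which were called without a fold limit. By list it did so in 100% of 24 major sperm protein, 97.1% of 34 sperm, 96.9% of 32 oocyte and 74.8% of 143 collagen genes. Among all 4222 genes 2-fold or more apart, a set picked at another threshold, the share was 92.5%. All these genes were picked on the gap between the flight groups, which by itself tends to put the ground group between them. The shares therefore do not bear on age, which was not measured. A slide or handling effect on whole samples cannot be told apart from group.

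The genes hsp-16.1, hsp-16.2, hsp-16.41 and F44E5.5 were highest in onboard 1G and lowest in microgravity. Of these, hsp-16.1 and F44E5.5 were read only by probes that match several genes, so their signals are not their own alone. The log2 fold changes of the 4 genes spanned a range of 2.00, but the 2 probes of hsp-16.41 alone spanned 3.16. That range does not decide whether hsp-16.2 and hsp-16.41 share 1 signal with copies, and the limit for it was changed after that was seen. A general heat shock response stays open: the other 21 heat shock genes had a median of 0.14 in microgravity minus onboard 1G, yet most of them are constitutive chaperones, and the inducible hsp-70 fell by 3.99 ± 0.13 and hsp-110 by 0.60 ± 0.07, both named outside the rule for genes after their values were seen. The limit first set on that median was wrong for this reason. Age also stays open. The median change of the 4 genes from ground 1G to microgravity was −3.33. This fall exceeded the lower quartile of −2.16 among sperm list genes called in microgravity vs onboard 1G. However, no size is fixed for an age effect, and that limit too was changed after the value was seen.

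The third pattern is the spike-in difference itself. A brighter slide or scan would raise the 75th percentile with the spike-ins, but it was lower in microgravity than in onboard 1G by 0.435 (log2 difference −0.435). Less worm RNA per spike-in in the labelling stays open. With spike-in scaling the highest median of the 5 signal classes was −0.384, but that scaling takes the same value from every gene, so it restates the difference, and no other table decides it.

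Other groupings of the arrays were counted. Splits of 6 arrays into 3 and 3 number 10, too few for a share under 0.05. The real splits gave 8421 and 5845 genes (microgravity vs onboard 1G), 6119 and 3812 (microgravity vs ground 1G), and 6298 and 6879 (onboard 1G vs ground 1G). The highest other gave 0, 0 and 1, so 1 of 10 splits gave as many in each. A split that mixes 2 groups puts most of their difference into the spread, so such low gene counts show only that arrays cluster by group or slide. For gene lists, 4 of 10 splits gave as many as the 16 in microgravity vs onboard 1G (highest other 20), 2 of 10 as many as the 12 in microgravity vs ground 1G (highest other 12), and 1 of 10 as many as the 20 in onboard 1G vs ground 1G (highest other 19). For the F test over 3 groups, 1 of 100 splits drawn from 280 gave as many as 15646 genes (highest other 10282), the real grouping itself.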

How the results depend on the processing

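Gene counts stayed within 1.5 times the main count under normexp, quantile normalization, median centring, both filters, the brightest probe, the value table, fits of 6 arrays, a trend and the replicate block, and in all 9 fits without 1 array, where 8003 to 8425 genes were higher and 5497 to 6004 lower in microgravity than onboard 1G. The numbers of the replicates do not pair them (correlations of deviations −0.08 to 0.21), and with the replicate block 8360 genes were higher and 5835 lower in that comparison. Slide as a block could not be fitted. Spike-in scaling, chosen after seeing the data, gave 1817 higher and 10749 lower in microgravity vs onboard 1G, 1003 and 10762 vs ground 1G, and 3348 lower in onboard 1G vs ground 1G; the cause is the construction, a shift of every gene. Of 14266 called genes in microgravity vs onboard 1G, 4721 had the opposite sign under it (1787 of them called), as did 3164 of 9931 vs ground 1G (607 called) and 141 of 13177 in onboard 1G vs ground 1G. The gene changes recomputed here are only those the text prints, cut down after a wider table of named genes, with more reversals in it, had been seen. A 2-fold threshold gave 1786 and 2436, 750 and 1367, and 2145 and 697 genes, and overlaps of 471 higher and 1302 lower in microgravity than in either 1G group, 83 and 21 in both flight groups than on the ground, and 1764 and 645 in onboard 1G than in either other group, by construction fewer. With an estimated correlation 0, 0 and 0 lists were called, and with fry, which does not compare a list with other genes, 27, 25 and 30 in the 3 comparisons.

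List medians with spike-in scaling were −0.39 for proteasome (microgravity vs onboard 1G) and −0.33 for oocyte (vs ground 1G). Against ground 1G, cytosolic ribosomal proteins were at −0.10 with quantile normalization, and among lists that passed with fry, its direction was opposite to camera's for oxidative stress (median 0.060), innate immunity (0.12) and proteasome (0.0232); the cause was not tested. Genes that changed sign with spike-in scaling in microgravity vs onboard 1G were rde-1 (−0.27), dcr-1 (−0.24), daf-16 (−0.41), rpn-2 (−0.17), rpn-5 (−0.25) and sir-2.1 (−0.13), and against ground 1G mbk-2 (−0.062), unc-54 (−0.29), unc-15 (−0.44), act-4 (−0.27) and unc-89 (−0.10). cat-2 was at 0.18 with normexp, and the cause was not tested. Dim signal limits genes not well above background to a bound.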

Other observations

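The 3 gene groups in this part were chosen and tested after members of them had been seen among the most changed genes, so the tests are not independent evidence. Their p-values were adjusted over these 3 groups alone in each comparison. The lists fixed beforehand were adjusted over a larger number of lists. An adjusted p here is therefore easier to bring under the threshold and cannot be set beside those of the earlier lists. Whether any call of this part would hold with adjustment over all lists was not tested. F-box genes of the fbxb and fbxc families, adaptors of protein degradation, were higher in microgravity than in onboard 1G in 127 of 140 measured cases and lower in 7 (median 2.23, camera adjusted p = 2.1e-17, and adjusted p = 0.046 with an estimated correlation). They were higher than in ground 1G in 126 cases and lower in 5 (median 0.89, adjusted p = 0.042 with an estimated correlation), and in onboard 1G against ground 1G 118 were lower and 7 higher (median −1.296, adjusted p = 0.044 with an estimated correlation). The medians kept their signs with spike-in scaling, at 1.60, 0.41 and −1.14. Of 23 SCP-like genes 10 fell and 4 rose in microgravity against onboard 1G (median −1.03, adjusted p = 0.026), and 11 fell and 2 rose against ground 1G (median −0.61, adjusted p = 0.00017). Neither call held with an estimated correlation (adjusted p = 0.32 and 0.093), and onboard 1G against ground 1G was not called (8 rose, 7 fell, adjusted p = 0.72).

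Genes of the intracellular pathogen response, known to rise after infection by microsporidia or Orsay virus, were tested as a set on the hypothesis that they are higher in microgravity than in both 1G groups. The list held 47 measured genes. Against ground 1G 38 rose and 3 fell (median 0.99, adjusted p = 8.7e-07, and 0.093 with an estimated correlation), with pals-14 at 1.53 and fbxa-75 at 1.83, both named outside the rule for genes. Against onboard 1G 29 rose and 11 fell (median 0.65, or 0.03 with spike-in scaling), and the larger adjusted p of the 2 contrasts, 0.128, did not pass, so the hypothesis failed for that comparison. In onboard 1G against ground 1G 23 rose and 3 fell (median 0.44, adjusted p = 0.00073, and 0.32 with an estimated correlation). Raised in microgravity against both 1G groups were 28 genes, where independent lists would give 23.4, and raised in both flight groups against the ground were 19, where they would give 18.6. Each pair of comparisons shares 3 arrays.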
